A study of Mus musculus with 20 samples.

How the data were processed

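The values analysed were FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) of 22564 protein-coding genes in 20 libraries, as deposited by the authors in a single table. Per the labels' protocols, ribosomal RNA was depleted from total RNA and libraries were made with a directional kit. The submitters' notes name cutadapt 1.9.3, HISAT2 2.0.4, Cufflinks, Cuffdiff and the genome build mm10, without the use of each. The annotation, strand use and any filters are not given in the sources used here. The FPKM were not scaled to a common total, and their sums ranged from 113544 to 171689 in heart and from 136461 to 208611 in muscle. Lars2 alone took 5.28 to 10.3% of the sum in heart and 7.33 to 19.2% in muscle. Its share was lowest in heart mdx and muscle wild-type replicate 2, which had the most genes of their tissue at 1 FPKM or more. The table also holds values far below that of 1 fragment, and exact zeros that can be failed estimates: mt-Nd1 was listed at 0 in all heart libraries but treated replicate 1, where it was at 17220 FPKM, and up to 8 genes per library were at 0 while their median in the other libraries of that tissue was 5 FPKM or more. A gene at 0 in every library of a group is therefore described as listed at 0, with each library's value and no fold, while log2 changes are given where only part of a group is at 0. 1 line of the table had been emptied and was not analysed here.

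Counts were not used here, so no count model was fitted. The depth was read from the steps between low values of genes with a single transcript of at least 3000 bases: 75.7 to 88.7% of these low values lay within 4% of a whole number of steps, which gave the implied fragments per library. Heart trans/mdx without UAA replicate 1 had 25.5% of its step values at 1 step, where the other heart libraries had 33.0 to 52.0%. Gene coordinates are those of a GENCODE annotation of mm10, written 1-based, and span the whole gene with exons, introns and UTRs. Of the deposited gene identifiers 21839 were found in it, and 80.4% of these start within 5000 bases of the position in the deposited table.

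Groups were taken from the labels. The strain label is C57BL/10 for mdx mice and C57BL/6N for the others, so strain and the mdx group cannot be separated. Replicates are separate mice. No pair of libraries was identical, and libraries of a group correlated at r of 0.855 to 0.896 in heart and 0.851 to 0.890 in muscle, across genes, which are not independent replicates.

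FPKM were transformed as log2(FPKM + 1). Genes with 1 FPKM or more in at least 2 of the libraries fitted were tested, which left 8269 in heart, 9126 in muscle and 10085 over both tissues. Each tissue was fitted with limma 3.58.1 (R 4.3.3), with a coefficient per group, 5 residual degrees of freedom and an intensity trend, and contrasts were tested two-sided with Benjamini-Hochberg adjustment at 0.05. Differences between the tissues were tested in a fit of all 20 libraries with 10 residual degrees of freedom. These choices, 42 gene lists of pathways and cell types, and the rule for genes named in the text were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, for lists with 5 or more tested members, adjusted over the lists of each contrast. With the estimated correlation the calls that held were those of adipocyte genes in heart, for mdx and for transgenic against wild type, for treated trans/mdx against transgenic mice and for the difference of the mdx effect. In muscle 13 of 36 lists passed with the preset correlation for mdx against wild type, 13 for transgenic against wild type and 11 for treated trans/mdx against transgenic mice. For the lists described, the highest adjusted p over the alternatives was that with an estimated correlation, except for fast fibre genes in treated hearts (0.342 and 0.770), immediate early genes in treated against transgenic muscle (0.510), fast fibre, mitochondrial genome and ribosomal protein genes in mdx muscle (0.990, 0.796 and 0.981) and calcium handling in transgenic muscle (0.937). Among differences between effects the exceptions were the mitochondrial genome in muscle (0.981), the mitochondrial genome and atrial genes for UAA in muscle minus heart (0.671 and 0.662), and Schwann cell and nerve genes (0.315). A list's relative median is its median log2 change minus that of all tested genes, because that median differed from 0 by over 0.1 in several contrasts.

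Named genes were, per tissue and comparison, the 3 with the smallest p in each direction where fewer than 5 passed (otherwise the 8 largest changes per direction), up to 4 members with the smallest p from each list, and Dmd and Utrn. Genes named outside this rule are marked as such. The gene called in muscle between all mdx-carrying and non-carrying mice is not reported here. For signatures of mdx, the 200 genes with the smallest p in each direction were used because fewer than 10 were called.

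The tests were run on simulated data with known changes of 5 sets per comparison. For mdx against wild type in heart (8269 genes), 4.47% of genes changed by a log2 of 1 were recovered, 45.8% at 2 and 71.9% at 3. For UAA treatment these were 5.03, 46.8 and 73.7% in heart and 5.70, 51.5 and 70.3% in muscle (9126 genes), and for mdx against wild type in muscle 6.55, 54.6 and 70.3%. For the comparison of 6 with 4 libraries they were 34.4, 88.0 and 93.7% in heart and 39.3, 89.3 and 91.0% in muscle. False calls over the 5 sets numbered 28, 24 and 42 in heart and 31, 36 and 35 in muscle for mdx against wild type, UAA treatment and 6 against 4 libraries. A list of 15 genes shifted by a log2 of 1 was found in 5 of 5 sets with both correlations. A list without a shift was called in 1 set, for 6 against 4 muscle libraries. Simulated genes varied independently and list p-values were unadjusted, so these sets cannot show how often lists of correlated genes are called falsely.

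Alternatives were a pseudocount of 0.1 FPKM, no filter, quantile normalization, median-of-ratios scaling, a replicate block, leaving out each library, a fit of only the libraries compared and a fit of all 20 libraries. A filter on a mean of 5 FPKM or more was added after seeing the data. Figures were drawn with matplotlib 3.10.9.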

Results

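RNA was sequenced from heart and tibialis anterior muscle of mice in 5 groups, with 2 mice per group and 20 libraries in all. The groups were wild-type mice, transgenic mice, mdx mice, and trans/mdx mice kept without or given an unnatural amino acid (UAA). Transgenic mice carry a system that places a UAA at a stop codon. Mdx mice carry a nonsense mutation in Dmd, the gene of the membrane-associated protein dystrophin, and are a model of Duchenne muscular dystrophy. Trans/mdx mice come from a cross of both lines, and treated animals received 50 mg of the lysine derivative NAEK every few days for 4 weeks. Low FPKM values implied 3030000 to 4090000 fragments per heart library and 1950000 to 2530000 per muscle library. A single fragment on a transcript of 1 kb then equalled 0.244 to 0.33 FPKM in heart and 0.395 to 0.513 in muscle, so levels near or below 1 FPKM rest on few fragments. With 2 mice per group, limma p-values rest on the spread within groups, pooled over the 5 groups of a tissue and moderated across genes. List p-values at the preset correlation compare genes with other genes and do not measure the spread between animals. With an estimated correlation 93 of 97 list calls were lost. Log2 changes refer to log2(FPKM + 1), which understates the change of genes with low levels.

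Dmd (X:82948870-85206141, mm10) was read first, as the gene that differs by genotype. Its level was 7.65 and 15.1 FPKM in mdx hearts, beside 14.7 and 12.0 in wild-type hearts, and 33.7 and 22.0 FPKM in mdx muscle beside 16.5 and 34.6 in wild-type muscle. The log2 change between mdx and wild type was -0.28 (SE 0.44) in heart and 0.18 (SE 0.40) in muscle, smaller than its error in both tissues, so the transcript level did not separate the genotypes. Utrn, the gene of the dystrophin-related protein utrophin, lay at 2.84 to 5.68 FPKM in heart and 2.40 to 4.46 in muscle, with log2 changes between mdx and wild type of 0.02 (SE 0.43) and -0.33 (SE 0.36). Myh6, the atrial and ventricular myosin of the adult mouse heart, was at 721 FPKM or more in every heart library and at 1.98 or less in every muscle library. Acta1, the skeletal actin, lay at 2214 to 5620 FPKM in muscle and 6.00 to 15.4 in heart. The Y-linked genes Ddx3y and Eif2s3y were above 0 in all 20 libraries. The pair of muscle libraries titled as the cross carries the genotype label of transgenic mice, and these were placed with trans/mdx without UAA by their titles.

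In hearts of mdx mice against wild-type mice, Pttg1 (11:43420250-43426251), which encodes securin, an inhibitor of separase, was listed at 0 FPKM in both mdx libraries and at 11.4 and 18.1 FPKM in wild type. It passed with an adjusted p of 0.000565 in limma, while zeros in this table can be failed estimates. Cyfip2 (11:46193850-46312859), a component of the WAVE actin-regulating complex, lay at 0.438 and 0.381 FPKM against 7.17 and 6.58 (log2 change -2.48, SE 0.41, adjusted p = 0.0563). Bmp10, a growth factor gene of atrial cardiomyocytes, was at 0 and 0.417 FPKM against 6.84 and 7.18 (-2.75, SE 0.44, adjusted p = 0.0563). Adipocyte genes were lower in mdx as a group: 10 of 11 lay below the median of all genes, with a list median of -0.87 relative to it. Examples were Scd1, a fatty acid desaturase, at 1.19 and 0.952 FPKM against 11.5 and 8.28, and Car3, a carbonic anhydrase abundant in fat, at 0 and 0.534 against 4.72 and 6.58. Camera gave this list an adjusted p of 3.59e-13, and adjusted p = 0.0159 with an estimated correlation. Adjusted over the list alone, 5 members were lower (Adipoq, Fasn, Car3, Scd1 and Cfd, where Fasn was named after its values were seen), while none passed over all genes.

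Blood and atrial genes moved in opposite directions in the same comparison. Erythrocyte genes had a relative median of 1.05 in mdx hearts (camera adjusted p = 0.00867, and adjusted p = 0.983 with an estimated correlation), with Hba-a1 at 64.0 and 68.3 FPKM against 30.8 and 21.9. The globin genes Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical pairs whose shares of reads are uncertain. Atrial genes had a relative median of -0.52 (adjusted p = 0.00313, and adjusted p = 0.983 with an estimated correlation). In total 1 of 8269 genes was called, and 219 had an unadjusted p under 0.05, where 413 were expected by chance. Pttg1 was below the threshold in every alternative tried. Cyfip2 passed with a pseudocount of 0.1 FPKM, quantile normalization or median-of-ratios scaling (adjusted p = 0.0473, 0.0340 and 0.0326). It also passed with all 20 libraries in a fit or only the 4 compared (0.0151 and 0.0116). Bmp10 passed in this last pair of fits (0.00344 and 0.00466). It was at 0 in all 10 muscles, which narrows its error in the fit of all 20 libraries. Scd1 and Car3 passed with only the 4 compared (0.0203 for each). So did Hist1h4c and Trappc2l, which were higher in mdx (0.00671 and 0.0343). The erythrocyte call ended with no filter (adjusted p = 0.160) or without wild-type replicate 2 (0.113), and the atrial call without wild-type replicate 1 (0.257) or mdx replicate 1 (0.161) and with a mean of 5 FPKM or more (0.656).

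**Figure D1:**
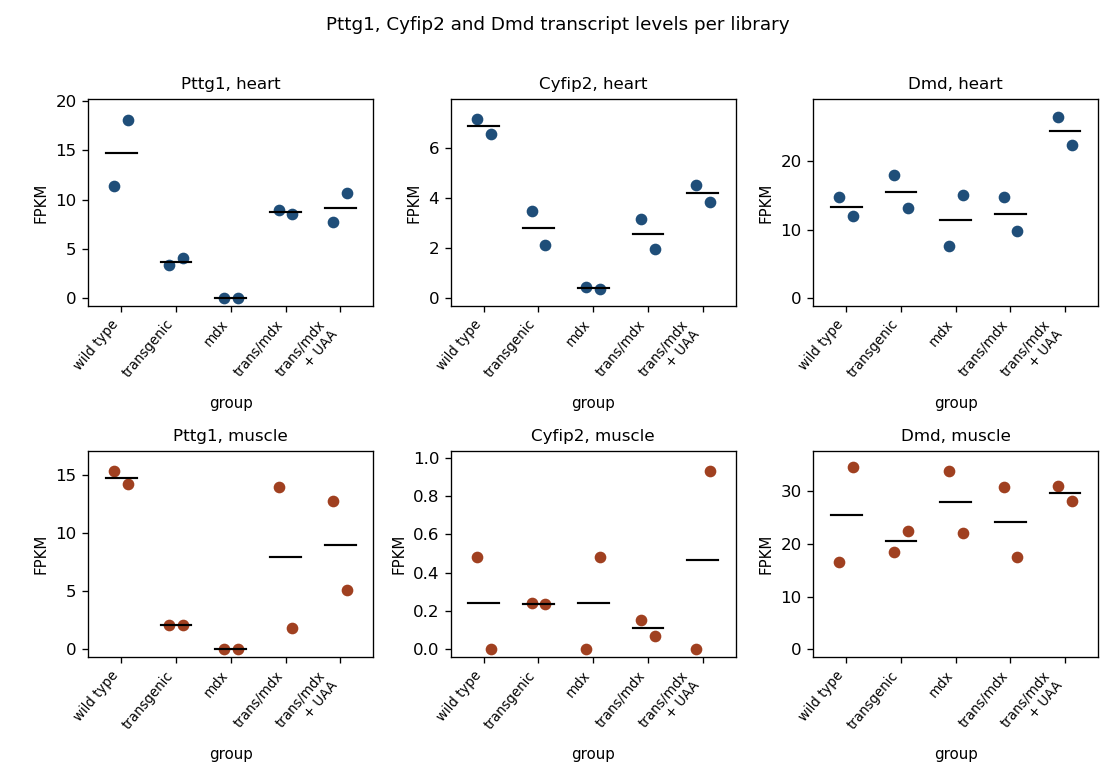
FPKM (vertical axis, linear) of Pttg1, Cyfip2 and Dmd in each heart library (upper panels) and muscle library (lower panels) by group; points are libraries and lines are means of 2. Pttg1 was listed at 0 in all 4 mdx libraries and above 0 in the other 16, and Cyfip2 in heart was at 0.438 and 0.381 FPKM in mdx.

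The comparison of transgenic with wild-type hearts shows what carrying the incorporation system goes with. Scd1 (19:44394455-44407879) fell to 0.514 and 0.182 FPKM from 11.5 and 8.28 in wild type (log2 change -3.01, SE 0.41, adjusted p = 0.0173). Other adipocyte genes were also low: Cfd, which encodes adipsin, and Adipoq, which encodes adiponectin, were listed at 0 in both transgenic hearts, against 3.73 and 4.17 FPKM and 1.58 and 3.91 FPKM in wild type. The list's relative median was -1.37 with 9 of 11 members below that of all genes (camera adjusted p = 1.99e-13, and adjusted p = 0.0152 with an estimated correlation). Adjusted over the list alone, 6 members were lower, and over all genes Scd1 alone. Immediate early genes had a relative median of -0.38 (adjusted p = 0.00914, and adjusted p = 0.968 with an estimated correlation), with Egr1 at 2.77 and 1.79 FPKM against 9.10 and 6.81. Myh7, the slow myosin re-expressed in stressed mouse ventricle, was at 9.03 and 7.03 FPKM against 2.63 and 2.83 (1.26, SE 0.41), and did not pass the threshold (adjusted p = 1). Tyrobp, an adaptor of macrophage receptors, was listed at 0 in both transgenic hearts and at 3.31 and 3.67 FPKM in wild type (adjusted p = 0.461).

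In this comparison 1 of 8269 genes was called and 279 had an unadjusted p under 0.05. The call of Scd1 ended without transgenic replicate 1 or 2, without wild-type replicate 1 or 2, with a pseudocount of 0.1 FPKM, with no filter, in a fit of all 20 libraries and in a fit of the 4 libraries compared, and its adjusted p ranged from 0.0173 to 1. The immediate early call ended without transgenic replicate 1 (adjusted p = 0.0546) or wild-type replicate 1 (0.135).

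**Figure D2:**
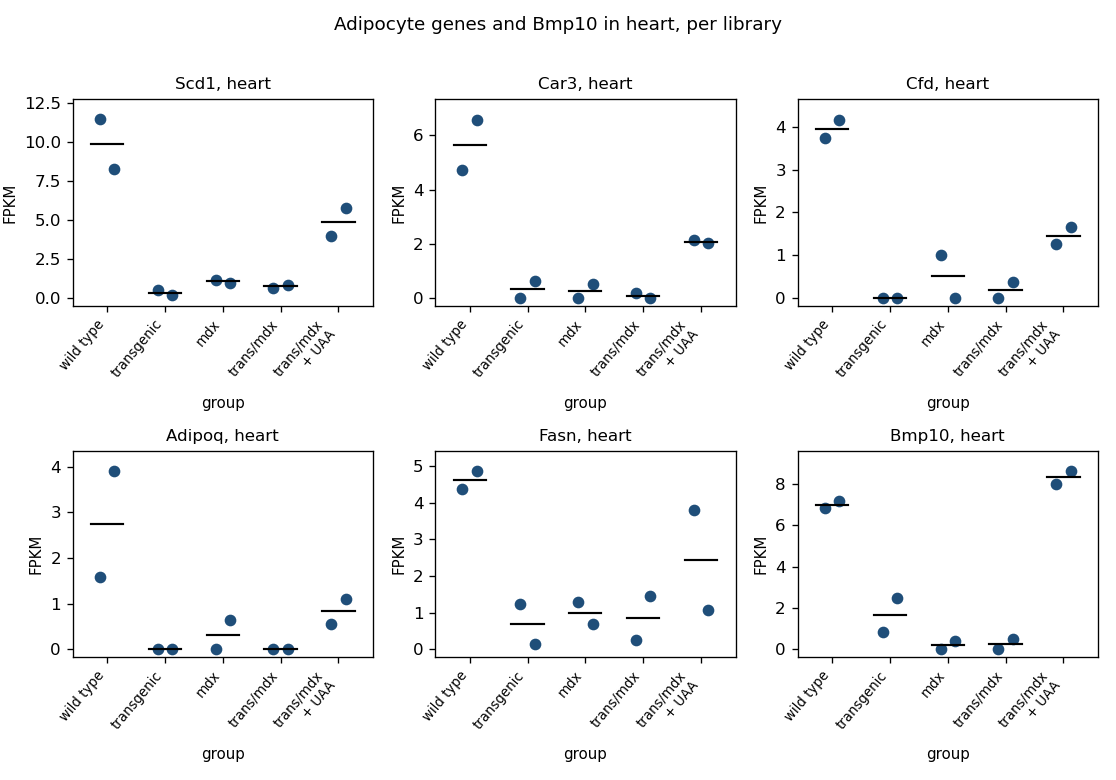
FPKM (vertical axis, linear) of 5 adipocyte genes and Bmp10 in each heart library by group; points are libraries and lines are means of 2. Scd1 lay at 11.5 and 8.28 in wild type and 4.00 and 5.78 in treated trans/mdx hearts, and at 1.19 or less in the other 6 libraries.

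Trans/mdx hearts without UAA were compared with transgenic hearts to see the mdx mutation among mice that all carry the system. All 8 atrial genes lay below the median of all genes, with a relative median of -0.62 (camera adjusted p = 0.00454, and adjusted p = 0.999 with an estimated correlation). Sln, the atrial calcium pump inhibitor sarcolipin, was at 0.703 and 8.46 FPKM against 20.4 and 16.0, and Myl4, the atrial myosin light chain, at 4.04 and 4.82 against 22.4 and 11.2. Macrophage genes had a relative median of -0.32 with 11 of 12 below (adjusted p = 0.0401, and adjusted p = 0.812 with an estimated correlation), and C1qc, a complement subunit made by macrophages, was listed at 0 in both trans/mdx hearts against 2.59 and 1.93 FPKM. Fatty acid oxidation genes had a relative median of -0.26 with 25 of 28 below (adjusted p = 0.0460, and adjusted p = 0.999 with an estimated correlation). Pdk4, a kinase that restrains glucose oxidation, was at 6.89 and 6.19 FPKM against 19.1 and 15.7. Ywhag, a 14-3-3 protein gene, had the smallest p, at 0.00112 and 0.415 FPKM against 10.6 and 7.33 (adjusted p = 0.426, or 0.00506 with only the 4 libraries compared).

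Limma called 0 of 8269 genes here, with 345 at an unadjusted p under 0.05, and the median of all genes was -0.11. The fatty acid and macrophage calls ended without any of several libraries, trans/mdx replicates 1 and 2 without UAA among them (adjusted p = 0.0883 and 0.470, and 0.149 and 0.127). The fatty acid call also ended without transgenic replicate 1, either treated heart or either wild-type heart (0.767, 0.0962, 0.0615, 0.0737 and 0.0732), the macrophage call without transgenic replicate 2 or either treated heart (0.205, 0.120 and 0.0564), and the atrial call without trans/mdx replicate 1 (0.105). With a pseudocount of 0.1 FPKM the fatty acid call ended (0.0656), and with no filter the macrophage call (0.228).

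Between trans/mdx hearts without UAA and mdx hearts, which both carry the Dmd mutation, Pttg1 was the called gene: it was at 8.95 and 8.54 FPKM in trans/mdx and listed at 0 in both mdx hearts (adjusted p = 0.00615). The strain labels also differ, with mdx mice labelled C57BL/10 and trans/mdx mice C57BL/6N. Macrophage genes were lower in trans/mdx, with 11 of 12 below the median of all genes and a relative median of -0.69 (camera adjusted p = 0.000127, and adjusted p = 0.155 with an estimated correlation). Lyz2, the lysozyme of macrophages, was at 1.52 and 3.92 FPKM against 10.2 and 12.9, and C1qc and Fcer1g were listed at 0 in both trans/mdx hearts against 2.78 and 3.34 FPKM and 2.02 and 3.45 FPKM in mdx. Adjusted over the list alone, these 3 genes were lower, and over all genes C1qc passed with a pseudocount of 0.1 FPKM (adjusted p = 0.0284). Extracellular matrix genes had a relative median of -0.30 with 22 of 26 below (adjusted p = 0.00119, and adjusted p = 1 with an estimated correlation), as with Postn, a matrix protein gene of activated fibroblasts, at 3.28 and 1.87 FPKM against 10.1 and 8.59. Genes of complement and MHC class II had a relative median of -0.53 (adjusted p = 0.0253, and adjusted p = 1 with an estimated correlation), with Cd74 at 4.98 and 3.01 FPKM against 12.2 and 9.21. Immediate early genes had -0.61 (adjusted p = 0.00838), nuclear genes of oxidative phosphorylation -0.24 (adjusted p = 0.00119), ribosomal protein genes -0.36 (adjusted p = 0.00119) and genes of the mitochondrial genome 0.45 (adjusted p = 0.00312), and each had adjusted p = 1 with an estimated correlation. Sgca, a sarcoglycan of the dystrophin complex, was at 2.07 and 2.56 FPKM against 7.54 and 11.6 (-1.65, SE 0.41, adjusted p = 0.410).

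Limma called 1 of 8269 genes, 479 had an unadjusted p under 0.05, of which 430 were lower, and the median of all genes was -0.26. The call of Pttg1 ended in a fit of all 20 libraries and without either trans/mdx or either mdx heart, and its adjusted p ranged from 7.40e-05 to 0.134. Without trans/mdx replicate 1, which had an unusual distribution of low values, the median of all genes was -0.42. The matrix call ended without trans/mdx replicate 2 (adjusted p = 0.122) or mdx replicate 1 (0.101) and with a mean of 5 FPKM or more (0.0731), and that of complement without these or treated replicate 2 (0.255, 0.235 and 0.106). The calls of oxidative phosphorylation, the mitochondrial genome and ribosomal proteins ended without mdx replicate 2 (0.954, 0.954 and 0.725), that of the mitochondrial genome also without trans/mdx replicate 1 (0.385), with no filter (0.0781) and with quantile normalization (0.431), and that of ribosomal proteins also without trans/mdx replicate 1 (0.0556). Oxidative phosphorylation also ended without trans/mdx replicate 2 (0.0552), and immediate early genes without trans/mdx replicate 1 or 2 or mdx replicate 1 (0.0556, 0.0670 and 0.0639).

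The effect of the 4 weeks of UAA was read from treated against untreated trans/mdx hearts. Bmp10 (6:87428994-87437677) was at 8.01 and 8.64 FPKM with UAA and at 0 and 0.499 without (log2 change 2.93, SE 0.44, adjusted p = 0.0608). All 8 atrial genes lay above the median of all genes, with a relative median of 0.88 (camera adjusted p = 7.33e-06, and adjusted p = 0.302 with an estimated correlation), among them Myl4 at 14.3 and 21.2 FPKM against 4.04 and 4.82. All 11 adipocyte genes lay above it too, with a relative median of 0.71 (adjusted p = 7.33e-06, and adjusted p = 0.116 with an estimated correlation), and Scd1 was at 4.00 and 5.78 FPKM against 0.655 and 0.854. Genes of fast skeletal fibres had a relative median of 1.05 (adjusted p = 7.33e-06, and adjusted p = 0.302 with an estimated correlation): Tnnt3, the fast troponin T, was at 7.04 and 2.76 FPKM against 0 and 0.343, and Myh4, the myosin of the fastest fibres, at 2.64 and 2.39 against 0.205 and 0. Adjusted over the lists alone, 3 atrial, 2 adipocyte and 4 fast fibre genes were higher, and none over all genes. Of 16 listed fast fibre genes 8 passed the filter in heart. Tnnt3, Myh4 and Atp2a1 did so only through the treated hearts, where they had 1 FPKM or more. The fast fibre result can therefore follow in part from that filter. In a fit of all 20 libraries Bmp10 and Tnnt3 passed (adjusted p = 0.00141 and 0.0152). Their error there also rests on the muscles (Bmp10 at 0, Tnnt3 at 3683 to 6350 FPKM), so neither pass is support.

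Immediate early genes, which respond to stimuli within minutes, were higher with UAA, with 14 of 15 above the median of all genes and a relative median of 0.70 (adjusted p = 8.61e-06, and adjusted p = 0.302 with an estimated correlation). Nr4a1, a nuclear receptor of this class, was at 5.91 and 4.81 FPKM against 1.23 and 0.866. Glucocorticoid-responsive genes had a relative median of 0.26 (adjusted p = 0.00701, and adjusted p = 0.886 with an estimated correlation), with Mt2, a metallothionein gene, at 23.1 and 16.4 FPKM against 1.25 and 3.77, which passed with a mean of 5 FPKM or more (adjusted p = 0.0205). All 11 genes of the mitochondrial genome lay below the median, at -0.45 (adjusted p = 3.85e-05, and adjusted p = 0.398 with an estimated correlation), for example mt-Nd5 at 7039 and 7193 FPKM against 12930 and 7616. Dmd itself was at 26.4 and 22.4 FPKM with UAA and 14.8 and 9.73 without (0.96, SE 0.44, unadjusted p = 0.0431, adjusted p = 0.823). Over all genes, limma called 0 of 8269 genes, 497 had an unadjusted p under 0.05, of which 392 were higher, and the median of all genes was 0.15. Trans/mdx replicate 1 without UAA had an unusual distribution of low values, and without it the median was 0.33. The fast fibre call ended without either treated heart (adjusted p = 0.342 and 0.237) and the glucocorticoid call without treated replicate 1 (0.144).

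**Figure D3:**
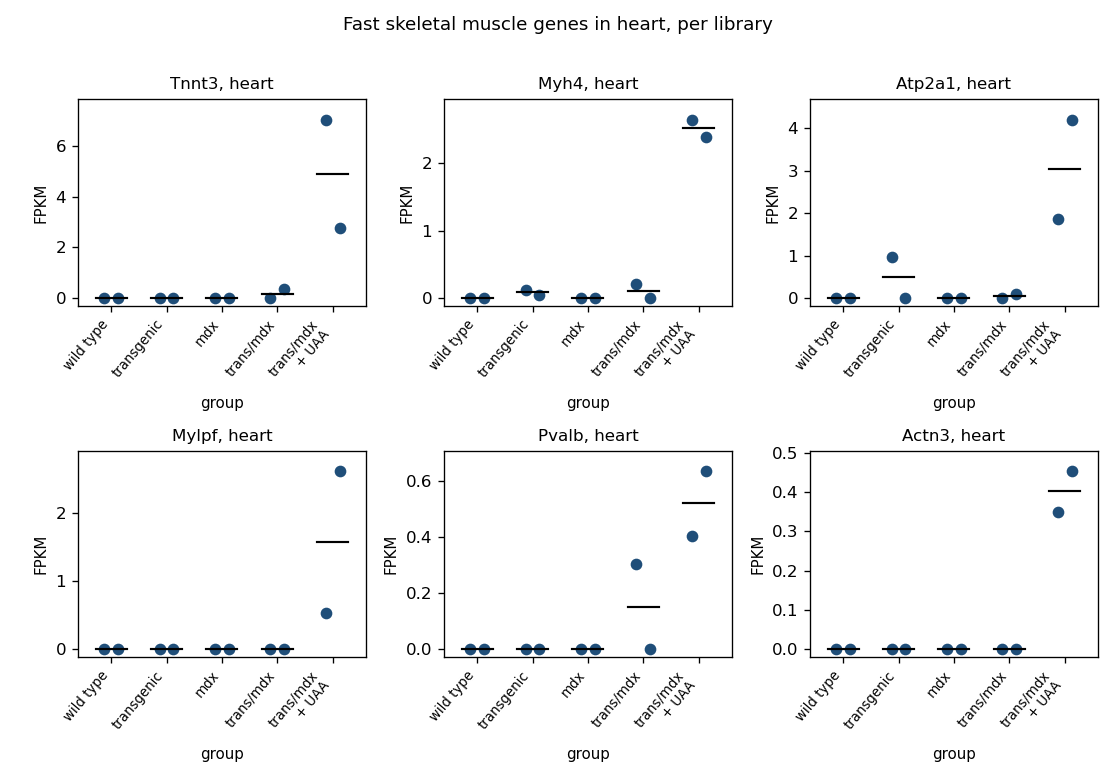
FPKM (vertical axis, linear) of 6 fast skeletal muscle genes in each heart library by group; points are libraries and lines are means of 2. Myh4 was at 2.64 and 2.39 in treated trans/mdx hearts and at 0.205 or less in the other 8 libraries.

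Treated trans/mdx hearts were also set against transgenic hearts, to see what differed from that control after UAA. Adipocyte genes were higher, with 10 of 11 above the median of all genes and a relative median of 0.93 (camera adjusted p = 1.03e-08, and adjusted p = 0.0412 with an estimated correlation). Adjusted over the list alone, 3 were higher (Scd1, Cfd and Car3), and Cfd was at 1.26 and 1.66 FPKM where transgenic hearts were listed at 0. Fast fibre genes had a relative median of 0.36 (adjusted p = 0.000226, and adjusted p = 0.697 with an estimated correlation). Here too Tnnt3, Myh4 and Atp2a1 passed the filter only through the treated hearts, which can raise that median. Immediate early genes had 0.49 (adjusted p = 0.00447, and adjusted p = 0.893 with an estimated correlation). Nr4a1 was at 5.91 and 4.81 FPKM against 1.15 and 0.615, and Bmp10 at 8.01 and 8.64 against 0.846 and 2.48 (1.88, SE 0.44, adjusted p = 0.624). Gene by gene, limma called 0 of 8269 genes, with 317 at an unadjusted p under 0.05. The fast fibre and immediate early calls ended without treated replicate 1 (adjusted p = 0.758 and 0.143) or 2 (0.770 and 0.152).

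Over all hearts, the 6 libraries of mdx-carrying mice were compared with the 4 others. Hamp, the gene of the iron hormone hepcidin, was listed at 0 in all 6 carrying hearts (adjusted p = 0.539). In the 4 others it was at 4.79, 1.32, 1.15 and 1.32 FPKM. In a fit of all 20 libraries its adjusted p was 0.0242, but it was at 0 in all 10 muscles, so this is no support. Isg20, an interferon-induced exonuclease gene, was at 0 to 0.823 FPKM in the former and at 1.63 to 2.31 in the latter (log2 change -1.10, SE 0.28, adjusted p = 1). Hba-a1 lay 0.97 higher (SE 0.26, adjusted p = 1) and erythrocyte genes had a relative median of 0.26 (camera adjusted p = 0.0425, and adjusted p = 0.877 with an estimated correlation). All 8 atrial genes lay below the median of all genes, at -0.36 (adjusted p = 0.0115, and adjusted p = 0.877 with an estimated correlation). Limma called 0 of 8269 genes, with 261 at an unadjusted p under 0.05. The erythrocyte call ended without any of 7 libraries, which were treated replicate 2 (adjusted p = 0.336), transgenic replicates 1 and 2 (0.123 and 0.0637), untreated replicate 2 (0.0804), wild-type replicates 1 and 2 (0.0722 and 0.177) and mdx replicate 2 (0.0565), and with no filter (0.0685). The atrial call ended without transgenic replicate 1 (0.114) or wild-type replicate 1 (0.0771).

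A further test set the mdx change in mice with the system against that in mice without it. The former is trans/mdx without UAA against transgenic, and the latter mdx against wild type. The mdx group alone differs in strain label, so a difference here cannot be separated from strain. In heart, Pttg1 differed: it was at 8.95 and 8.54 FPKM against 3.36 and 4.05 in carriers of the system, and at 0 against 11.4 and 18.1 in non-carriers (adjusted p of the difference 0.00241). The call ended with no filter and in a fit of all 20 libraries, and its adjusted p ranged from 0.000198 to 0.0503. Scd1 (2.77, SE 0.58), already at 0.514 and 0.182 FPKM in transgenic hearts, and C1qc (listed at 0 in trans/mdx) did not pass, with adjusted p = 0.637 for both. In heart the median difference of all genes was -0.18 and in muscle 0.40, and in heart 304 of 8269 genes had an unadjusted p under 0.05. The heart median was -0.34 without untreated trans/mdx replicate 1, and the muscle median 0.14 without wild-type replicate 2. In muscle limma called 0 of 9126 genes, with 704 at an unadjusted p under 0.05, and Pttg1 had an adjusted p of 0.510. It passed there in a fit of all 20 libraries (0.0226) and without trans/mdx replicate 2 (0.0101), and ranged from 0.0101 to 0.834, so that no contrast between the tissues follows.

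In muscle, mdx was compared with wild type. Ece1 (4:137862237-137965229), which encodes the endothelin-converting enzyme, was at 5.38 and 3.61 FPKM against 27.9 and 27.7 (log2 change -2.41, SE 0.35, adjusted p = 0.135). Pttg1 was listed at 0 in both mdx muscles and at 15.3 and 14.2 FPKM in wild type (adjusted p = 0.166, and 0.000897 to 0.540 over the alternatives). It passed without trans/mdx replicate 1 or 2 of the untreated mice (0.0104 and 0.00953), with a pseudocount of 0.1 FPKM (0.0237), a mean of 5 FPKM or more (0.0360), all 20 libraries (0.00532) and only the 4 compared (0.000897). Ece1 passed with a mean of 5 FPKM or more (0.0217) and all 20 libraries (0.0405). Macrophage genes were higher than the bulk of genes in mdx muscle, with 9 of 12 above the median and a relative median of 0.59 (camera adjusted p = 0.000864, and adjusted p = 0.718 with an estimated correlation), and genes of complement and MHC class II had 0.68 (adjusted p = 0.00123, and adjusted p = 0.718 with an estimated correlation). Cd74, the MHC class II invariant chain, was at 5.13 and 10.2 FPKM against 1.77 and 3.70. Lyz2 was at 2.36 and 14.1 FPKM against 0.424 and 4.52. Nuclear genes of oxidative phosphorylation had a relative median of -0.30 with 32 of 41 below (adjusted p = 1.70e-05, and adjusted p = 0.718 with an estimated correlation), and fatty acid oxidation genes -0.37 (adjusted p = 0.000713, and adjusted p = 0.718 with an estimated correlation). Fabp3, a fatty acid carrier, was at 64.9 and 27.3 FPKM against 122 and 149, and Mstn, which encodes the growth inhibitor myostatin, at 6.00 and 2.60 against 12.2 and 21.1 (-1.77, SE 0.41, adjusted p = 0.348).

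Markers of regenerating fibres had a relative median of 0.49 (adjusted p = 0.0382, and adjusted p = 0.718 with an estimated correlation), and Myh3, the embryonic myosin, was at 0 and 1.76 FPKM in mdx and 1.76 or less in all muscle libraries. Neutrophil and mast cell genes had 0.94 (adjusted p = 0.0275, and adjusted p = 0.718 with an estimated correlation), and S100a8, S100a9 and Ngp were at 40.7, 37.2 and 31.2 FPKM in mdx replicate 2 and at 0 in mdx replicate 1. Without mdx replicate 2 the medians were -0.28 for regenerating fibres and -0.47 for neutrophils (adjusted p = 0.626 and 0.638), and the macrophage (0.453), complement (0.0764) and fatty acid (0.0997) calls ended. The calls of regenerating fibres and neutrophils also ended without wild-type replicate 2 (0.637 and 0.216), and that of complement without wild-type replicate 1 (0.213). Quantile normalization ended the calls of macrophages (0.0746), regenerating fibres (0.259), neutrophils (0.366) and oxidative phosphorylation (0.196, relative median -0.10), and median-of-ratios scaling ended the same calls (0.0611, 0.313, 0.444 and 0.0611). The calls of regenerating fibres and neutrophils also ended with no filter (0.137 and 0.166), and that of neutrophils with a pseudocount of 0.1 FPKM (0.0962).

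Other lists called in mdx against wild-type muscle had relative medians of -0.07 for fast fibre genes, -0.02 for the mitochondrial genome, -0.17 for glycolysis, -0.32 for heat shock, -0.23 for clock and -0.19 for ribosomal protein genes (camera adjusted p = 0.00851, 0.0459, 0.00851, 0.00851, 0.0182 and 0.00851, and adjusted p = 0.718 for each with an estimated correlation). The 5 tested atrial genes had 0.73 (adjusted p = 0.0128, and adjusted p = 0.718 with an estimated correlation). All 7 calls ended without wild-type replicate 2 (adjusted p = 0.105 to 0.637), with quantile normalization (0.0750 to 0.990) or with median-of-ratios scaling (0.0611 to 0.714), and all but that of glycolysis without mdx replicate 2 (0.0764 to 0.417). The glycolysis call ended without mdx replicate 1 (0.109), the atrial call with no filter (0.0585), and the other 6 with a mean of 5 FPKM or more (0.176 to 0.790). The fast fibre median was 0.01 without wild-type replicate 2 and 0.02 to 0.06 with a pseudocount of 0.1 FPKM, either scaling or a mean of 5 FPKM or more. Genes of the mitochondrial genome passed in a single alternative, without wild-type replicate 1, where their median was 0.10 (0.0190).

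Over all genes, limma called 0 of 9126 genes in muscle between mdx and wild type, with 921 at an unadjusted p under 0.05, of which 861 were lower, and the median of all genes was -0.35. Wild-type replicate 2 stood apart, with 8530 genes at 1 FPKM or more against 6794 to 7002 in the other 9 muscle libraries. Without it the median of all genes was -0.09, and -0.32 without mdx replicate 2. The same library enters every wild-type comparison in muscle.

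Transgenic muscle against wild-type muscle differed in tendon and matrix genes. Tendon genes had a relative median of -1.82 with 6 of 7 below the median of all genes (camera adjusted p = 0.00107, and adjusted p = 0.518 with an estimated correlation), and adjusted over the list alone 5 were lower (Kera, Thbs4, Comp, Chad and Fmod, where Comp was named after its values were seen). Thbs4, a matrix protein of tendon and muscle, was at 2.43 and 1.43 FPKM against 14.4 and 20.7 (log2 change -2.66, SE 0.52, adjusted p = 0.247). Extracellular matrix genes had a relative median of -0.42 with 24 of 31 below (adjusted p = 0.000107, and adjusted p = 0.836 with an estimated correlation), with Col1a1, a chain of type I collagen, at 5.79 and 6.09 FPKM against 26.1 and 45.0 (-2.35, SE 0.40, adjusted p = 0.167). Ece1 was at 4.22 and 5.79 FPKM against 27.9 and 27.7 (-2.27, SE 0.35, adjusted p = 0.167). In a fit of all 20 libraries Ece1, Col1a1 and Thbs4 passed (adjusted p = 0.0491, 0.0311 and 0.0491), with a mean of 5 FPKM or more Ece1 and Col1a1 (0.0418 and 0.0423), and with only the 4 libraries compared Fmod (0.0141). Oxidative phosphorylation genes had a relative median of -0.31 with 34 of 41 below (adjusted p = 8.64e-07, and adjusted p = 0.836 with an estimated correlation), with Cox8b, a cytochrome oxidase subunit, at 53.2 and 68.8 FPKM against 130 and 224.

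Macrophage genes in transgenic muscle had a relative median of 1.03 (adjusted p = 1.82e-05, and adjusted p = 0.501 with an estimated correlation), and genes of complement and MHC class II 0.68 with 11 of 11 above (adjusted p = 1.82e-05, and adjusted p = 0.501 with an estimated correlation). Lyz2 was at 6.26 and 8.75 FPKM against 0.424 and 4.52. Neutrophil and mast cell genes had 0.91 (adjusted p = 0.00329, and adjusted p = 0.501 with an estimated correlation) and cytokine genes 0.84 (adjusted p = 0.00643, and adjusted p = 0.501 with an estimated correlation). Igfn1, which encodes a protein of the muscle Z-disc, was at 17.0 and 21.6 FPKM against 0.739 and 3.56 (2.84, SE 0.68, adjusted p = 0.372). Gene by gene, limma called 0 of 9126 genes, with 904 at an unadjusted p under 0.05. The median of all genes was -0.33, and -0.073 without wild-type replicate 2. The matrix call ended without wild-type replicate 2 (relative median -0.09, adjusted p = 0.0737), the tendon call without wild-type replicate 1 (0.0591), and the neutrophil call without transgenic replicate 1 (0.0556) or wild-type replicate 2 (0.0737). The neutrophil call also ended with no filter, quantile normalization or median-of-ratios scaling (0.0714, 0.0763 and 0.0972).

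Further lists called in transgenic against wild-type muscle had relative medians of -0.18 for fast fibre genes, -0.20 for calcium handling, -0.08 for glycolysis, 0.11 for atrophy and proteolysis, 0.29 for immediate early and 0.56 for adipocyte genes (camera adjusted p = 0.000943, 0.0396, 0.0134, 0.0401, 0.0126 and 0.0127, and adjusted p = 0.836 for each with an estimated correlation). All but the adipocyte call ended without wild-type replicate 2 (adjusted p = 0.155 to 0.385). Without wild-type replicate 1 the adipocyte median was -0.25 (0.642), and the atrophy call ended (0.0553). The calls of calcium handling, glycolysis and adipocytes ended without transgenic replicate 1 (0.163 to 0.181), and those of calcium handling, atrophy and immediate early genes without transgenic replicate 2 (0.109 to 0.323). The calcium handling call also ended without either untreated trans/mdx library (0.0520 and 0.0506). Either scaling ended the calls of fast fibres, calcium handling and glycolysis (0.499 to 0.937), where the glycolysis median was 0.004 and 0.04, as it was 0.04 with a pseudocount of 0.1 FPKM, which also ended the atrophy call (0.0518). No filter ended the calls of atrophy (0.161, median -0.02) and adipocytes (0.252), and a mean of 5 FPKM or more those of calcium handling, glycolysis, atrophy and adipocytes (0.586, 0.104, 0.537 and 0.0635).

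In trans/mdx muscle without UAA against transgenic muscle, macrophage genes had a relative median of -0.69 with 12 of 12 below the median of all genes (camera adjusted p = 0.00361, and adjusted p = 0.972 with an estimated correlation). Genes of complement and MHC class II had -0.68 (adjusted p = 0.00361, and adjusted p = 0.972 with an estimated correlation), with H2-Aa at 2.19 and 1.78 FPKM against 6.73 and 4.37. Aqp1, a water channel gene of endothelium, was at 19.9 and 26.4 FPKM against 9.78 and 7.03 (log2 change 1.36, SE 0.35, adjusted p = 1). Limma called 0 of 9126 genes, with 346 at an unadjusted p under 0.05. The macrophage call ended without transgenic replicate 1 (adjusted p = 0.0891) or trans/mdx replicate 1 (0.0926), and the complement call without transgenic replicate 2 (0.0878) or trans/mdx replicate 1 (0.0738) and with no filter (0.0650).

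Between trans/mdx muscle without UAA and mdx muscle, extracellular matrix genes were lower in trans/mdx, with 29 of 31 below the median of all genes and a relative median of -0.47 (camera adjusted p = 2.24e-06, and adjusted p = 0.946 with an estimated correlation). Postn was at 0.972 and 0.784 FPKM against 3.61 and 3.45, and Mgp, the matrix Gla protein gene, at a mean of 1.02 against 9.42 (log2 change -2.34, SE 0.42, adjusted p = 0.381). All 14 adipocyte genes lay above the median, at 0.78 (adjusted p = 2.83e-05, and adjusted p = 0.946 with an estimated correlation), with Cfd at 30.3 and 66.4 FPKM against 4.59 and 8.09. Genes of the mitochondrial genome had 0.31 (adjusted p = 0.00590, and adjusted p = 0.946 with an estimated correlation), with mt-Nd2 at 8209 and 10350 FPKM against 7754 and 5332. Igfn1 was at 37.5 and 9.85 FPKM against 0.829 and 2.27 (3.06, SE 0.68, adjusted p = 0.614). Over all genes, limma called 0 of 9126 genes, with 486 at an unadjusted p under 0.05. The adipocyte call ended without trans/mdx replicate 2 (adjusted p = 0.155), and the mitochondrial call without that library (0.386) or mdx replicate 2 (0.0613). With quantile normalization the mitochondrial median was 0.11 (0.241), and that call also ended with a mean of 5 FPKM or more (0.0667).

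UAA-treated against untreated trans/mdx muscle showed higher immediate early genes and lower adipocyte genes. Of 17 immediate early genes 15 lay above the median of all genes, at a relative median of 0.63 (camera adjusted p = 1.03e-07, and adjusted p = 0.983 with an estimated correlation). Adjusted over the list alone 5 were higher (Nr4a1, Dusp1, Nr4a2, Nr4a3 and Junb, where Nr4a1 was named after its values were seen), as with Nr4a3 at 9.73 and 4.94 FPKM against 0.803 and 1.53. All 15 glucocorticoid-responsive genes lay above the median, at 0.42 (adjusted p = 0.000234, and adjusted p = 0.983 with an estimated correlation), with Pdk4 at 40.0 and 65.9 FPKM against 21.4 and 19.4 (1.29, SE 0.36). Adipocyte genes had a relative median of -1.70 with 12 of 14 below (adjusted p = 1.29e-09, and adjusted p = 0.983 with an estimated correlation). Adjusted over the list alone 4 were lower (Retn, Adipoq, Plin1 and Cfd), and Cfd was at 4.12 and 7.78 FPKM against 30.3 and 66.4 (-2.78, SE 0.91), with 3.08 and 61.5 FPKM in the wild-type muscles. Genes of fibroblasts and fibro-adipogenic progenitors had -0.51 with 14 of 15 below (adjusted p = 0.00120, and adjusted p = 0.983 with an estimated correlation), with Dcn, the decorin gene, at 17.5 and 28.7 FPKM against 36.2 and 39.7.

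Fast fibre genes had a relative median of 0.19 in treated muscle (adjusted p = 0.0191, and adjusted p = 0.983 with an estimated correlation). With quantile normalization it was 0.0067 (adjusted p = 0.764). Without treated replicate 1 it was -0.01, and the immediate early (adjusted p = 0.0707) and fibroblast (0.196) calls ended. Without untreated replicate 2 the fibroblast (0.0568) and fast fibre (0.581) calls ended. Dmd was at 30.9 and 28.1 FPKM with UAA and 30.8 and 17.5 without (0.33, SE 0.40, adjusted p = 1), and without untreated replicate 2 the log2 change was -0.06. Gene by gene, limma called 0 of 9126 genes, with 364 at an unadjusted p under 0.05.

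Treated trans/mdx muscle was also compared with transgenic muscle. Retnla, a resistin-like gene of alternatively activated macrophages, was listed at 0 in both treated muscles against 4.58 and 7.82 FPKM (adjusted p = 0.188, or 0.0301 with a pseudocount of 0.1 FPKM). Genes of complement and MHC class II had a relative median of -0.89 with 11 of 11 below (camera adjusted p = 1.82e-05, and adjusted p = 0.492 with an estimated correlation). Macrophage genes had -0.92 (adjusted p = 3.60e-05, and adjusted p = 0.492 with an estimated correlation), fibroblast genes -0.72 (adjusted p = 3.60e-05, and adjusted p = 0.492 with an estimated correlation) and adipocyte genes -1.19 (adjusted p = 3.27e-06, and adjusted p = 0.492 with an estimated correlation). Lyz2 was at 0.405 and 1.23 FPKM against 6.26 and 8.75. Immediate early genes had 0.45 (adjusted p = 0.000846, and adjusted p = 0.492 with an estimated correlation) and glucocorticoid-responsive genes 0.32 (adjusted p = 0.00176, and adjusted p = 0.570 with an estimated correlation). The immediate early call ended without treated replicate 1 (adjusted p = 0.510) or transgenic replicate 1 (0.0740). Limma called 0 of 9126 genes, with 444 at an unadjusted p under 0.05.

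In the same comparison extracellular matrix genes had a relative median of -0.38, neutrophil and mast cell genes -1.09 and cytokine genes -0.82 with 5 of 5 below (camera adjusted p = 0.0293, 0.0293 and 0.00308, and with an estimated correlation adjusted p = 0.895, 0.492 and 0.492). Nuclear genes of oxidative phosphorylation had 0.12 and the mitochondrial genome 0.17 (adjusted p = 0.0463 and 0.0269, and with an estimated correlation adjusted p = 0.912 and 0.750). The calls of the matrix, oxidative phosphorylation and the mitochondrial genome ended without treated replicate 1 (adjusted p = 0.757, 0.510 and 0.314), transgenic replicate 1 (0.0832, 0.151 and 0.179) or transgenic replicate 2 (0.131, 0.175 and 0.0640). The first pair also ended without either mdx library (0.0543 to 0.0560), and oxidative phosphorylation without either untreated library (0.0539 and 0.0508). The neutrophil call ended without treated replicate 2 (0.212) or transgenic replicate 1 (0.183). Both scalings ended the calls of neutrophils (0.0785 and 0.0855), oxidative phosphorylation (0.534 and 0.120) and the mitochondrial genome (0.561 and 0.0855). No filter ended those of neutrophils and the mitochondrial genome (0.0708 and 0.0568), and a mean of 5 FPKM or more those of oxidative phosphorylation and the mitochondrial genome (0.208 and 0.162).

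Over all muscles, the 6 libraries of mice carrying the mdx mutation were set against the 4 of mice that do not. Extracellular matrix genes had a relative median of -0.15 with 23 of 31 below (camera adjusted p = 0.0132, and adjusted p = 0.971 with an estimated correlation), and Col1a1 had a log2 change of -1.38 (SE 0.26, adjusted p = 0.628). Nmrk2, a nicotinamide riboside kinase gene, was at 11.1 to 35.1 FPKM in the carrying libraries and 1.95 to 13.8 in the others (1.29, SE 0.28, adjusted p = 0.699). The 5 tested atrial genes, most of them scarce in muscle, had 0.58 (adjusted p = 0.0188, and adjusted p = 0.736 with an estimated correlation). In total 1 of 9126 genes was called, 507 had an unadjusted p under 0.05, and the median of all genes was -0.13. The gene call ended with a pseudocount of 0.1 FPKM, no filter, either scaling or a replicate block. Without wild-type replicate 2 the median of all genes was -0.0035. The matrix call ended without treated replicate 1, transgenic replicate 2, untreated replicate 1 or wild-type replicate 2 (adjusted p = 0.0697, 0.0852, 0.0824 and 0.344), and the atrial call without transgenic replicate 2, untreated replicate 1, wild-type replicate 2 or mdx replicate 2 (0.134, 0.0824, 0.344 and 0.111). The atrial call also ended with quantile normalization (0.0898) or median-of-ratios scaling (0.0616).

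**Figure D4:**
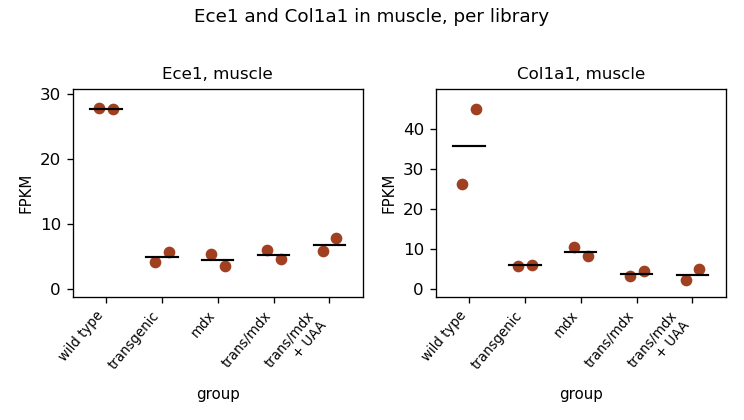
FPKM (vertical axis, linear) of Ece1 and Col1a1 in each muscle library by group; points are libraries and lines are means of 2.

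Whether effects differed between the tissues was tested as muscle minus heart. Bmp10 was listed at 0 in all 10 muscles, so that its differences are those of heart. Bmp10 had the smallest adjusted p for mdx against wild type (0.149) and for UAA treatment (0.142). Col1a1 had a log2 difference of -1.87 for mdx against wild type (SE 0.53, adjusted p = 0.795). Over all genes, limma called 0 of 10085 genes for mdx, UAA and mdx-carrying mice. In these tests 605, 460 and 346 had an unadjusted p under 0.05, and the medians of all genes were -0.39, -0.12 and -0.11. Without muscle wild-type replicate 2 the medians for mdx and for mdx-carrying mice were -0.14 and 0.0067. Without heart untreated trans/mdx replicate 1 that for UAA was -0.26. Scd1 passed for UAA treatment without muscle wild-type replicate 1 or 2 (adjusted p = 0.00630 and 0.00655), and its adjusted p ranged up to 1.

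The 200 genes per direction with the smallest p between mdx and wild type were followed into the crossed mice. In treated against untreated hearts the higher list had a median of 0.21 and the lower list of 0.20, or 0.05 relative to all genes for both (camera adjusted p = 0.388 for both). In untreated trans/mdx against transgenic hearts they had -0.14 and 0.01 relative to all genes (adjusted p = 0.238 and 0.516), where the test of the lower list pointed down while its relative median was above 0. In muscle the relative medians were 0.02 and 0.03 with UAA (adjusted p = 0.343 and 0.420) and -0.07 and 0.02 in untreated trans/mdx against transgenic mice (adjusted p = 0.140 and 0.605). The higher list had a median of -0.027 in the last comparison before that of all genes was subtracted. It passed without wild-type replicate 2 or mdx replicate 1, where that median was -0.09 and -0.07 (adjusted p = 0.0101 and 0.0270). With an estimated correlation the adjusted p of these 8 tests ranged from 0.674 to 0.829.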

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

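The tests on adipose tissue, atria, skeletal muscle transcripts and Pttg1 below were chosen after the result was seen, and those of differences between effects before the data were examined. The rule for single outlying libraries needs at least 4 in a group and was not applied to the groups of 2.

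The mdx effect differed with the incorporation system for Pttg1 in heart (adjusted p of the difference 0.00241 in limma). It did not pass with no filter or all 20 libraries in a fit (0.0503 for both). The mdx group alone differs in strain label, so such differences cannot be separated from strain, in heart or muscle. In heart, macrophage genes had a median difference of -0.56 relative to all genes (camera adjusted p = 0.0404, and adjusted p = 0.407 with an estimated correlation), which passed only with all 10 hearts or without transgenic replicate 1, and otherwise had adjusted p from 0.0621 to 0.232. Adipocyte genes had 1.11 (adjusted p = 9.03e-09, and adjusted p = 0.0406 with an estimated correlation). Transgenic hearts were already near 0 for several of them (Cfd and Adipoq at 0 in both, Car3 at 0 and 0.639 FPKM), so a further fall among carriers could not have shown, and the difference can follow from this low baseline.

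In muscle the same difference was -1.47 for macrophage genes, -2.11 for neutrophil genes, -0.99 for cytokine genes and -1.09 for genes of complement and MHC class II (adjusted p = 4.55e-06, 0.0290, 0.0425 and 4.68e-06, and adjusted p = 0.465 for each with an estimated correlation). It was 0.33 for nuclear genes of oxidative phosphorylation, 0.16 for the mitochondrial genome and 0.37 for circadian clock genes (adjusted p = 2.81e-05, 0.0425 and 0.0392, and adjusted p = 0.771 for each with an estimated correlation). The neutrophil call ended without transgenic replicate 1, untreated replicate 1, wild-type replicate 2 or mdx replicate 2 (0.137, 0.0515, 0.122 and 0.302). The cytokine call ended without either treated or untreated library or wild-type replicate 2 (0.0556 to 0.0780). The clock call ended without either treated library, transgenic replicate 1, untreated replicate 2, wild-type replicate 2 or mdx replicate 2 (0.0530 to 0.180). When a library was left out, the mitochondrial call held only without untreated replicate 1 or wild-type replicate 1, and without untreated replicate 2 the median was -0.06.

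These muscle differences also depended on the scaling. With quantile normalization and median-of-ratios scaling oxidative phosphorylation had 0.15 and 0.18 (adjusted p = 0.0938 and 0.0531) and the mitochondrial genome -0.0065 and 0.00094 (0.643 and 0.981), and the calls of clock (0.0938 and 0.0645), neutrophil (0.199 and 0.264) and cytokine genes (0.137 and 0.149) ended. The mitochondrial call also ended with a pseudocount of 0.1 FPKM (0.0597), with no filter (0.0834) and with a mean of 5 FPKM or more (0.553). With no filter the neutrophil difference was -0.47 (0.0985), with a pseudocount of 0.1 FPKM the cytokine call ended (0.0597), and with a mean of 5 FPKM or more the clock call (0.518).

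Muscle minus heart was tested in the same way. Of the 8 atrial genes Nppa, Myl7 and Bmp10 were at 0 in all 10 muscles and Sln in 5, so the atrial values in this and the next paragraphs largely carry the heart change and do not compare effects of both tissues. For mdx against wild type the difference was -0.29 for oxidative phosphorylation, 0.47 for adipocyte genes and 1.05 for atrial genes (adjusted p = 0.00379, 0.0395 and 1.72e-05, and with an estimated correlation adjusted p = 0.779, 0.779 and 0.196). The first ended without heart mdx replicate 2 (0.658), muscle wild-type replicate 2 (0.118) or muscle mdx replicate 2 (0.117). It was -0.073 with quantile normalization (0.683), -0.12 with median-of-ratios scaling (0.230) and -0.13 with a mean of 5 FPKM or more (0.0751). The adipocyte difference ended without either treated heart (0.0549 and 0.0542), heart wild-type replicate 2 (0.110), heart mdx replicate 2 (0.303) or muscle mdx replicate 1 (0.0563), and was -0.54 without muscle wild-type replicate 1 (0.552). It also ended with no filter, quantile normalization or median-of-ratios scaling (0.0813, 0.0738 and 0.0796).

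For UAA treatment the difference between muscle and heart was -0.58 for fibroblast genes, -0.24 for fast fibre genes, 0.47 for the mitochondrial genome, -1.66 for adipocyte genes and -0.77 for atrial genes (adjusted p = 0.00754, 0.00986, 0.00216, 5.60e-12 and 0.00216, and with an estimated correlation adjusted p = 0.973, 0.973, 0.484, 0.458 and 0.458). The fibroblast call ended without muscle treated replicate 1 (0.151) or untreated replicate 2 (0.0660), the fast fibre call without muscle treated replicate 2 (0.198) or untreated replicate 1 (0.0978), and the mitochondrial call without heart treated replicate 2 (0.671), heart untreated replicate 1 (0.110) or muscle untreated replicate 1 (0.0835). The atrial difference was -0.53 with a pseudocount of 0.1 FPKM (0.139) and -0.39 with a mean of 5 FPKM or more (0.662), where its call ended.

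For all mdx-carrying against non-carrying mice the difference was -0.20 for extracellular matrix genes, -0.30 for fibroblast genes, -0.25 for fast fibre genes, -0.34 for Schwann cell and nerve genes and 0.77 for atrial genes (adjusted p = 0.00229, 0.0335, 0.00982, 0.00982 and 5.99e-05, and with an estimated correlation adjusted p = 0.994, 0.994, 0.994, 0.134 and 0.134). The matrix call ended without muscle wild-type replicate 2 (0.124), the fast fibre call without that library, muscle treated replicate 2 or muscle transgenic replicate 2 (0.102, 0.0585 and 0.0581), and the Schwann cell call without muscle transgenic replicate 2 or wild-type replicate 1 (0.0581 and 0.0719). With no filter the Schwann cell difference was -0.048 (0.304), and its call ended with a pseudocount of 0.1 FPKM too (0.315). The fibroblast call ended without replicate 2 of treated, transgenic, untreated or wild-type hearts, and without muscle treated 1, transgenic 2, untreated 1, wild-type 2 or mdx 1 (0.0519 to 0.204).

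Scd1, Cfd, Adipoq, Car3 and Bmp10 were lower in each transgenic, mdx and untreated trans/mdx heart than in the wild-type hearts, and higher with UAA. Lipid synthesis genes of heart muscle alone stay open: Adipoq, Cfd and Car3, which do not make lipid, had a mean log2 change of -1.90 in mdx against wild-type hearts (SE 0.19), but they were picked from the genes that formed the pattern. Adipose tissue in the heart samples stays open as a candidate explanation: 7 of 8 ratios of Adipoq or Scd1 to Cfd in wild-type and treated hearts lay in the range of the muscle libraries. A smaller share of both atria could not be told apart from other causes. In transgenic against wild-type hearts Nppa, Myl7, Myl4 and Sln had a mean log2 change of -0.13 (SE 0.66), and Bmp10 fell by -1.66 (SE 0.38). The difference between them was 1.53 (SE 0.73), with an interval that includes 0. Whether the genotypes themselves differ in heart fat was not tested.

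Transcripts of fast skeletal muscle were seen in both UAA-treated hearts. The test took 9 genes abundant in muscle with a median in the other hearts of at most 0.02% of the muscle level. Of these 100% were above 0 in both, the result set for RNA or reads carried over from skeletal muscle. Genes switched on in the heart would be above 0 as well, and Tnnt3, Myh4 and Atp2a1 had formed the pattern. This outcome therefore does not favour carry-over. Pvalb, Tnnc2 and Mylpf, at 0.405, 0.599 and 0.533 FPKM in treated replicate 1, rest on few fragments. Tnni2, however, was higher in another heart than in both treated hearts (0.944 and 0.756 FPKM), and Atp2a1 was at 0.969 FPKM in another heart. The 9 genes summed to 0.0813 and 0.0833% of the muscle level in the treated hearts. The 0 to 0.0112% of the other hearts follows largely from how the genes were chosen and is no support. Fast-fibre genes switched on in the treated heart cannot be told apart from this, because the highest ratio of heart to muscle level was 5.57 times the lowest, between the limits set for either (Spearman rho 0.783 across genes, exact p = 0.0172, genes not being independent).

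Pttg1 was listed at 0 in all 4 mdx libraries. The Dmd mutation is argued against as the cause, since trans/mdx hearts without UAA carry it and had a log2 change of 1.05 against transgenic hearts (SE 0.41). A strain variant near Pttg1 on chromosome 11 may be the cause and could not be told apart from chance, with 1 of 16 other tested genes within 5 Mb at an unadjusted p under 0.01 (Cyfip2) against 48 of 8252 elsewhere (Fisher's exact test, one-sided, p = 0.0908). In muscle it was 1 of 13 against 204 of 9112 (Fisher's exact test, one-sided, p = 0.256). The strain label differs for the mdx group alone, so strain stays open and untested, as does whether the zeros are failed estimates.

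For the comparisons of 6 with 4 libraries, counts over other splits decide nothing. The real split called 0 genes in a fit of 2 groups in heart, in muscle and in their difference, so that 100 of 100 drawn splits had to give as many in each, and the highest of the other splits was 3, 4 and 2.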

How the results depend on the processing

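The filter on a mean of 5 FPKM or more was chosen after seeing the data, and the other alternatives were fixed before. Counts are of called genes, and the cause of each change was not tested. When a group keeps 1 library, that library is assumed to vary like the others. The mdx signatures already held the 200 genes of smallest p per direction, so that alternative was identical and tested nothing. Depth limits genes near 1 FPKM, which rest on a few fragments.

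With a pseudocount of 0.1 FPKM, heart calls were 2 for mdx against wild type, 0 for transgenic against wild type and 2 for untreated trans/mdx against mdx, and muscle calls 1 for mdx against wild type, 1 for untreated trans/mdx against mdx, 1 for treated trans/mdx against transgenic and 0 for all mdx-carrying against non-carrying mice. With no filter the heart counts were 4, 0 and 2 for the same comparisons and 0 for the difference of the mdx effect. With no filter muscle gave 3 for mdx against wild type, 3 for untreated trans/mdx against mdx and 0 for mdx-carrying mice, and muscle minus heart 8 for mdx, 1 for UAA and 2 for mdx-carrying mice. Quantile normalization gave 2 for mdx against wild type in heart, 0 for mdx-carrying mice in muscle and 1 for mdx in muscle minus heart, and median-of-ratios scaling 2 and 0 for the first pair.

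A mean of 5 FPKM or more gave 0 for transgenic against wild type and 2 for UAA in heart, and 2 for mdx and 2 for transgenic against wild type in muscle. All 20 libraries in a single fit gave in heart 3 for mdx and 0 for transgenic against wild type, 0 for untreated trans/mdx against mdx, 2 for UAA, 1 for treated trans/mdx against transgenic, 1 for mdx-carrying mice and 0 for the difference of the mdx effect, and in muscle 3, 7, 1 and 2 for mdx against wild type, transgenic against wild type, treated trans/mdx against transgenic and the difference. Only the 4 libraries compared gave in heart 8 for mdx against wild type, 1 for untreated trans/mdx against transgenic and 11 against mdx, and in muscle 1 for mdx and 1 for transgenic against wild type. With all 20 libraries, heart calls of Bmp10, Hamp and Tnnt3 rest in part on muscle values. Called lists numbered 4 with an estimated correlation and 35 with a mean of 5 FPKM or more.

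Leaving out each library in turn gave heart counts of 1 to 2 for mdx against wild type, 0 to 1 for transgenic against wild type, 0 to 2 for untreated trans/mdx against mdx, 0 to 1 for UAA and 1 to 2 for the difference of the mdx effect, and 0 to 0 for the other 3. Muscle counts were 0 to 1, with 0 to 3 for untreated trans/mdx against mdx and 0 to 2 for mdx-carrying mice, and those of muscle minus heart 0 to 1. In the same runs, the list of genes lower in mdx hearts had a median log2 change of -0.31 to 0.042 in untreated trans/mdx against transgenic hearts. The list of genes higher in mdx muscle had -0.17 to 0.019 in that comparison, and the higher and lower lists -0.0044 to 0.22 and -0.0060 to 0.073 with UAA. Dmd with UAA in muscle ranged from -0.060 to 0.72, regenerating fibres from -0.28 to 0.87 and neutrophils from -0.47 to 2.15 in mdx muscle, fast fibres with UAA in muscle from -0.014 to 0.42, the mitochondrial genome in the muscle difference from -0.063 to 0.36, and adipocytes in muscle minus heart from -0.54 to 0.95. The libraries whose omission reversed these were heart transgenic replicate 1 for the heart list, and in muscle untreated trans/mdx replicate 2 for Dmd, the mitochondrial genome and both lists with UAA, treated replicate 1 for fast fibres, mdx replicate 2 for regenerating fibres and neutrophils, and wild-type replicate 1 for adipocytes. The higher muscle list in untreated trans/mdx mice reversed without mdx replicate 2, untreated replicate 2 or transgenic replicate 1. In mdx against wild-type muscle fast fibres ranged from -0.21 to 0.0079 and the mitochondrial genome from -0.13 to 0.097, and in transgenic against wild-type muscle adipocytes from -0.25 to 1.16. Fast fibres reversed without wild-type replicate 2, the mitochondrial genome without wild-type replicate 1 or mdx replicate 2, and adipocytes without wild-type replicate 1.

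Reversed medians elsewhere, before that of all genes was subtracted, were 0.0037 for genes lower in mdx hearts, in untreated trans/mdx against transgenic hearts with quantile normalization, -0.026 for the muscle list with median-of-ratios scaling, and relative to all genes -0.0065 for the mitochondrial genome in the muscle difference with quantile normalization. In mdx muscle, with a pseudocount of 0.1 FPKM, quantile normalization, median-of-ratios scaling and a mean of 5 FPKM or more, they were 0.051, 0.024, 0.064 and 0.047 for fast fibres and 0.11, 0.035, 0.12 and 0.10 for the mitochondrial genome. In transgenic muscle glycolysis had 0.037, 0.0036 and 0.0405 with the first 3 of these, and atrophy and proteolysis -0.021 with no filter.

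With a replicate block, heart calls were 2 for mdx against wild type (Pttg1 and Bmp10) and 1 for UAA (Bmp10), and muscle calls 0 for mdx-carrying mice. List calls lost with it were fatty acid oxidation in untreated trans/mdx against transgenic hearts (adjusted p = 0.0624) and, in the muscle difference of the mdx effect, cytokines (0.0574), the mitochondrial genome (0.0819) and clock genes (0.0508). In muscle those of the mitochondrial genome for mdx (0.101) and calcium handling for transgenic against wild type (0.0604), and of oxidative phosphorylation in treated trans/mdx against transgenic mice (0.0661), were lost too. The replicate numbers did not pair the samples: deviations of equal numbers correlated at -0.061 to 0.039 across groups in heart, -0.051 to 0.038 in muscle and -0.020 to 0.013 between heart and muscle.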

Other observations

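A comparison chosen after the data were seen asked how often other pairings of libraries were as alike as the true groups. Over 945 ways to pair the 10 libraries of a tissue, 52 in heart and 23 in muscle had a mean within-pair correlation as high as the true groups (exact p = 0.0550 and 0.0243, one-sided). With a mean of 5 FPKM or more these were 99 and 91 (exact p = 0.105 and 0.0963). Correlations were taken after quantile normalization and centring of each gene. With the main filter the true groups had a mean of -0.089 in heart and -0.080 in muscle, against a median over pairings of -0.111 in both. Libraries of a group thus resembled each other little more than other pairs.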
